A study of Mus musculus with 2 samples.

How the data were processed

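Single-cell RNA was measured in live CD45+ cells of the gastric mucosa of TxA23 mice with 10x Genomics 5' chemistry. Mice received 800 ng of recombinant IL-27 (4 ug per mL in 200 uL) or PBS from pumps placed at 3 months of age and worn for 4 weeks. Per the submitters' processing notes the authors used Cell Ranger 3.0.0 with mm10, while the matrix headers name software version 3.1.0. The deposited matrices hold raw UMI counts per gene and barcode, per the file headers and the values, which were whole numbers. The IL-27 library pooled 3 females and the PBS library 1 female and 1 male, per the labels. Gene IDs were looked up in GENCODE M21 (Ensembl 96, GRCm38, the build also called mm10), where 31011 of 31053 were present and 77 of 77 named genes were found. Noct, for example, is ENSMUSG00000023087 on chromosome 3 at 51224447 to 51251644, plus strand.

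The IL-27 library held 20897 barcodes and 80121995 UMIs, and the PBS library 12276 barcodes and 43501501 UMIs. Cells needed at least 200 detected genes and at most 10% mitochondrial UMIs, which removed 43 and 313 IL-27 barcodes and 30 and 478 PBS barcodes, with some failing both. Doublets were called by Scrublet (in scanpy) at its automatic threshold. The plan named a call per library, but since barcode suffixes showed separate wells the call was made per well. It marked 4.17%, 2.53% and 2.00% of the IL-27 wells, 1.58% of PBS well 1 and 0.0183% of PBS well 2 (1 cell). A call under 0.5% was treated as not having worked, so no cell of PBS well 2 was removed, against 607 IL-27 and 100 PBS well 1 cells. The wells then held 7234, 5862 and 6876 IL-27 cells and 6242 and 5451 PBS cells, with median UMIs of 2836, 3160.5, 3161.5, 2747 and 3149. Median genes per cell were 1346 in IL-27 and 1291 in PBS.

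Both libraries were clustered together without batch correction, on counts per 10000 after log1p, 2000 variable genes (without antigen receptor, sex-linked, mitochondrial, ribosomal protein and haemoglobin genes), 30 components, 15 neighbours and Leiden resolution 1. Clusters were named from fixed markers only. A marker set needed a mean of 0.3 of the highest cluster's level and at least 3 detected markers, and CD4 and CD8 T-like clusters a 5-fold difference between Cd4 and Cd8a. These thresholds were set after the data had been seen. Other clusters stayed numbered. Cells with Xist and no Y-linked UMI (Ddx3y, Uty, Kdm5d, Eif2s3y) were called female, the reverse male, and the rest were left out of that split.

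Shares were given with exact binomial 95% intervals, and expression as UMIs summed per class and group, in CPM over all genes, with exact Poisson intervals. Ratios had exact conditional intervals, and log2 ratios a pseudocount of 1 CPM. The design has 1 library per group, so the comparisons fixed before the data were examined carried no test. Gene lists of T helper, regulatory, cytotoxic, interferon, antigen presentation, stress, metabolic and contaminating cell types were fixed at the same time. List members needed at least 10 CPM in the higher library and 20 UMIs, and lists at least 5 members. Each list's median was placed among 10000 random lists matched on expression in 20 bins, and its range came from 2000 resamplings of its members. Named genes were the 12 highest and 12 lowest log2 ratios in CD4 T-like cells and 5 and 5 in other classes of at least 200 cells, of which 3 and 3 may be given. They needed at least 50 CPM, 100 UMIs and 10% of the gene's highest CPM in any class of at least 50 cells, and antigen receptor, sex-linked, mitochondrial, ribosomal protein, haemoglobin and unnamed genes were left out. List members and a few fixed genes, among them Il27ra, Il6st, Stat3, Il10, Ifng, Il17a, Foxp3 and Cd4 could be named as well. Igkv12-44, Igkv1-117, Igkv3-2, Igkc, Iglv1, Arl5a, Igkv5-43, Ighv9-1, Eif2s3y, Ddx3y, Gpr25, Litaf and Cd79a, and Noct and Myb in classes where the rule did not take them, were named after their values were seen.

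Wells as replicates were added after the files were seen. UMIs summed per well and class were tested with the edgeR quasi-likelihood test after TMM scaling and filterByExpr, and with DESeq2, at an adjusted p of 0.05. Shares were compared by exact two-sided permutation. Alternatives varied the cell filters, doublet handling, clustering, the choice of CD4 T-like cells, sex, scaling, depth (cells thinned to 1000 UMIs), list filters and pseudocount, and left out each well in turn.

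The methods were tested on simulated data. With 200 genes given known folds, edgeR on simulated CD4 T-like wells recovered 38.8% of 1.5-fold, 80.6% of 2-fold and 95.5% of 4-fold changes and called 13 of 10071 unchanged genes. DESeq2 recovered 28.4%, 67.2% and 95.5% and called 9. Among simulated ratios, intervals held the true value for 94.0% of 1.5-fold, 94.0% of 2-fold and 93.9% of 4-fold genes. Of lists of 15 unchanged genes, 90.0% fell between percentiles 2.5 and 97.5 in a first run of 20 lists. The number was then raised to 200 after that result was seen, and 97.0% fell there. A list raised 1.5-fold reached percentile 100. The ratio and list simulations held counting error only, so they do not cover differences between wells or mice. In the simulated wells all wells shared the same spread and genes varied independently, so a well that stands apart was not modelled.

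Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. Myeloid classes were too small or unnamed for expression comparisons and were left out of them.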

Results

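TxA23 mice carry a T cell receptor transgene and develop autoimmune gastritis. Live CD45+ cells of the gastric mucosa were compared between 3 female mice given IL-27 and 2 mice given PBS, 1 female and 1 male, by pumps worn for 4 weeks from 3 months of age. Each group was deposited as 1 library, and the barcode suffixes split the IL-27 library into 3 wells and the PBS library into 2. PBS well 1 held no UMI of 4 Y-linked genes and PBS well 2 held 3138, so they are called the female and the male PBS well, although the labels do not state that a well is a mouse. All IL-27 wells lacked Y-linked UMIs. After filtering, 19972 IL-27 cells and 11693 PBS cells remained, with median depths of 3053 and 2946 UMIs.

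T-lineage cells made up more of the IL-27 library, and B-like and NK-like cells made up less of it. Conventional CD4 T-like cells, the class to which the transgenic receptor belongs, were 18.2% of IL-27 cells (95% interval 17.7 to 18.8, 3638 cells) and 9.49% of PBS cells (8.97 to 10.0, 1110 cells), a ratio of 1.92 (1.79 to 2.05). Treg-like cells, which restrain autoimmunity, were 4.95% against 3.61%, a ratio of 1.37 (1.22 to 1.54), which reversed to 0.920 with a doublet score threshold of 0.25 in every well, an alternative chosen after the data had been seen. B-like cells were 44.6% against 53.1%, a ratio of 0.840 (0.813 to 0.868), and NK-like cells 1.16% against 2.29%, a ratio of 0.507 (0.423 to 0.606). All T clusters together were 37.4% against 22.8%, a ratio of 1.64 (1.57 to 1.72).

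The CD4 T-like share differed widely between the PBS wells. It was 20.3%, 18.2% and 16.01% in the IL-27 wells, 14.6% in the female PBS well and 3.69% in the male PBS well. Without PBS well 2 the CD4 T-like ratio was 1.25, and without PBS well 1 it was 4.94. Every IL-27 well lay above both PBS wells for CD4 T-like and Treg-like cells and below both for B-like and NK-like cells. Treg-like shares were 5.42%, 4.38% and 4.93% against 4.10% and 3.05%. NK-like shares were 1.20%, 1.47% and 0.858% against 1.60% and 3.08%. In exact two-sided permutation tests of the mean share over the 3 IL-27 and 2 PBS wells, p was 0.1 for CD4 T-like, Treg-like and NK-like cells and 0.2 for B-like cells. The wells make 10 splits, so 0.1 is the smallest p possible and no share could pass 0.05. These p-values measure only the spread between wells, and the intervals cover counting error only.

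**Figure D1:**
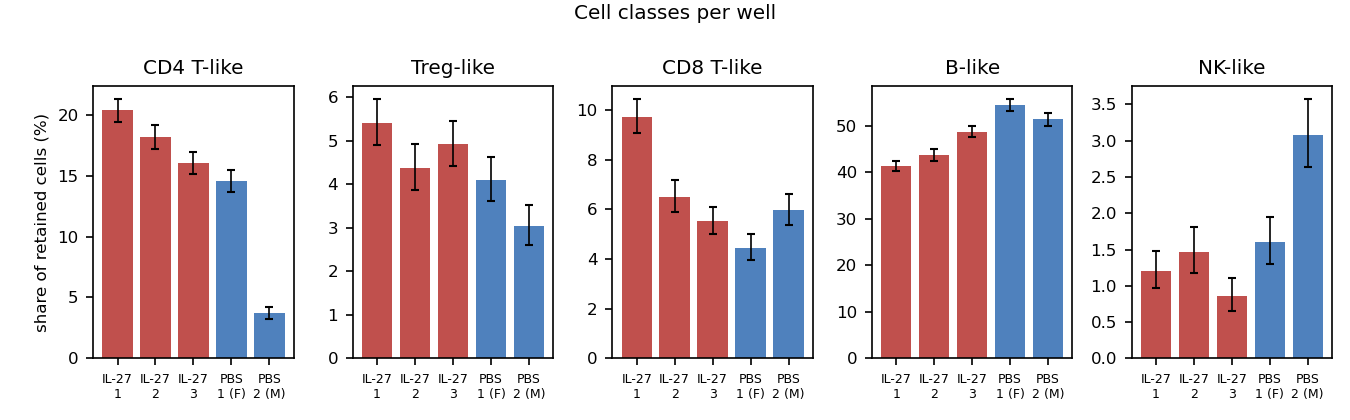
Shares of retained cells (%) in CD4 T-like, Treg-like, CD8 T-like, B-like and NK-like classes, with 1 bar per well (IL-27 in red, PBS in blue, F female, M male) and exact 95% binomial intervals. CD4 T-like cells were 16.01% to 20.3% of the IL-27 wells, 14.6% of the female PBS well and 3.69% of the male PBS well.

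CD8 T-like cells, the cytotoxic T lineage, were 7.34% of IL-27 cells and 5.16% of PBS cells, a ratio of 1.42 (1.29 to 1.57), but the class held a pair of unlike clusters. Cluster 5 was 9.68%, 6.16% and 5.42% of the IL-27 wells, 4.34% of PBS well 1 and 0.550% of PBS well 2. Cluster 15 was 5.41% of PBS well 2 and at most 0.341% of any other well, and it made up 90.8% of the CD8 T-like cells of PBS well 2. The exact permutation p of the CD8 T-like share over the 5 wells was 0.4 (two-sided). Mast cell-like cells, which release mediators of allergy, numbered 11 in the IL-27 library and 140 in the PBS library, of which 136 came from PBS well 2 (2.49% of that well). The mast cell-like ratio of IL-27 over PBS was 0.0460, and without PBS well 2 it was 0.859. Cluster 22, an unnamed T cluster, had 132 of its 163 cells in PBS well 2.

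**Figure D2:**
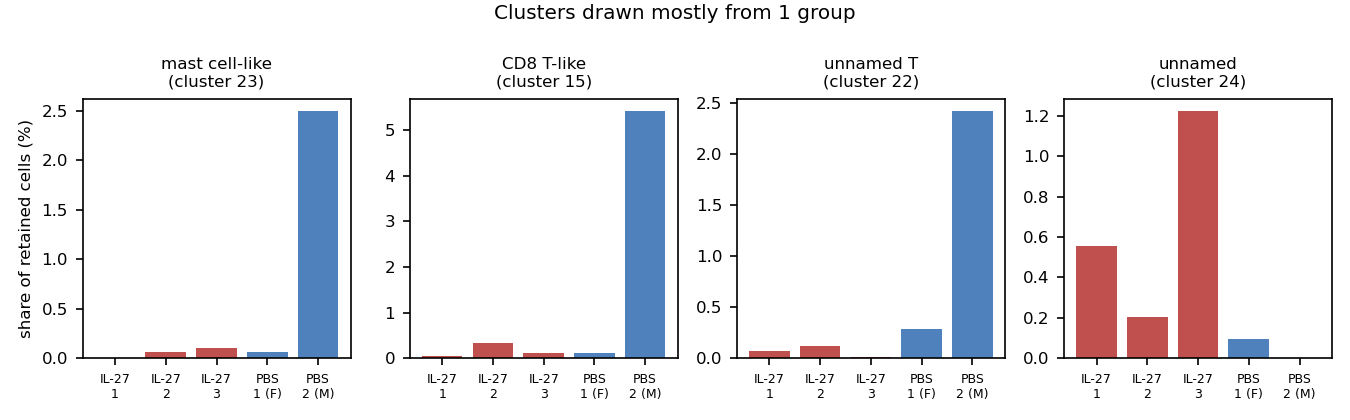
Shares of retained cells (%) in 4 clusters, with 1 bar per well (IL-27 in red, PBS in blue, F female, M male). Mast cell-like cells, cluster 15 and cluster 22 came mostly from PBS well 2 (2.49%, 5.41% and 2.42%), and cluster 24 was 0.205% to 1.22% of the IL-27 wells.

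Smaller classes were also unequal between PBS wells. Plasmacytoid dendritic-like cells, known as interferon producers, were 0.496% of IL-27 cells and 0.924% of PBS cells, with 1.58% in PBS well 2 and 0.352% in PBS well 1. Gamma-delta T-like cells were 0.190% of IL-27 cells, 0.240% of PBS well 1 and 0.881% of PBS well 2, and ILC2-like cells 0.335%, 0.401% and 0.660%. Neutrophil-like cells were 0.220%, 0.160% and 0.642%, mature dendritic-like cells 0.145%, 0.0961% and 0.349%, and plasma cell-like cells 0.180%, 0.144% and 0.0917% in the same order. Unnamed clusters outside the T lineage held 15.2% of IL-27 cells and 17.9% of PBS cells, and unnamed T clusters 6.91% and 4.53%. The naming threshold behind these shares was set after the data had been seen. Counting the unnamed clusters of the B lineage, B-lineage cells were 58.4% against 69.6%.

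Splitting cells by Xist and Y-linked UMIs separated the PBS mice in another way. CD4 T-like cells were 19.3% of female-called IL-27 cells (2779 of 14432), 16.7% of female-called PBS cells (766 of 4593) and 3.61% of male-called PBS cells (78 of 2162). Among female-called cells the CD4 T-like ratio of IL-27 over PBS was 1.16 and the NK-like ratio 0.715. Treg-like cells were 5.13% of female-called IL-27 cells, 3.55% of female-called PBS cells and 3.24% of male-called PBS cells. The male well also held 183 female-called cells, 32 of them among its 201 CD4 T-like cells. Xist was found in 70.7% of PBS well 1 cells, so 183 is likely an undercount. At that detection rate they would be 4.75% of the male well. Values of the whole male well, its CD4 T-like share among them, include these cells.

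Within CD4 T-like cells, gene expression in the IL-27 wells lay closer to the female PBS well than the male PBS well did. Among 2572 genes, 1 or 2 were at least 2-fold apart between any pair of IL-27 wells, and 2 to 5 between an IL-27 well and PBS well 1. Between PBS well 2 and an IL-27 well the number was 34 to 43, and between the PBS wells it was 43. Treg-like cells had the same order, with 5 to 9 of 2923 genes between IL-27 wells, 6 to 15 against PBS well 1, 91 to 153 against PBS well 2 and 120 between the PBS wells. B-like cells of every well were close, with 0 to 4 of 2631 genes apart in any pair. In NK-like cells the counts were 134 to 187 of 3095 genes between IL-27 wells and 118 to 149 against PBS well 1. Against PBS well 2 the number was 74 to 139, and between the PBS wells 84. NK-like wells held only 59 to 168 cells, with the most in PBS well 2, so counting error weighs on these counts. They cannot show whether PBS well 2 stands apart in this class. The CD4 T-like cells of PBS well 2 came mostly from cluster 9 (143 of 201 cells), which gave 156 of the 909 in PBS well 1.

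**Figure D3:**
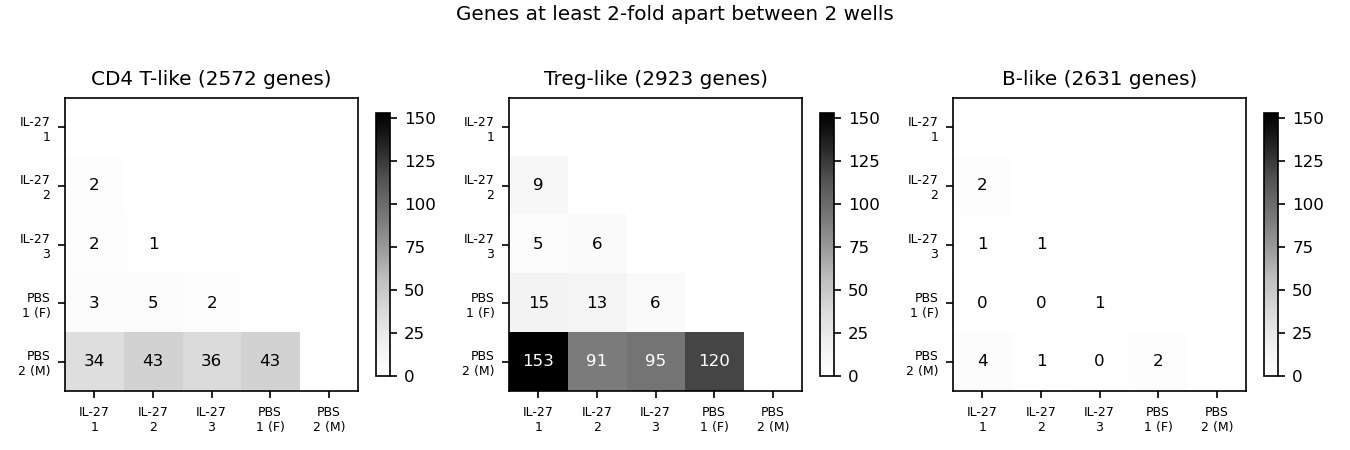
Number of genes at least 2-fold apart (grey scale and printed counts) between each pair of wells in CD4 T-like, Treg-like and B-like cells, wells on both axes. PBS well 2 stands apart from every other well in CD4 T-like (34 to 43 genes) and Treg-like cells (91 to 153).

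IL-27 binds a receptor of Il27ra and Il6st and activates Stat3 among other factors, and CD4 T-like cells of both groups held these 3 transcripts. Il27ra was 230 CPM in IL-27 and 207 in PBS, and Stat3 114 in IL-27, 103 in PBS well 1 and 140 in PBS well 2. Il6st was 204 CPM in IL-27, 209 in PBS well 1 and 119 in PBS well 2, with a log2 ratio of 0.089, and 0.77 without PBS well 1. The IL-27 receptor and ligand list had a median log2 ratio of 0.06 over 8 members. The interferon response list, which IL-27 can induce, had a median of -0.10 over 31 members (resampled range -0.19 to -0.02), below all 10000 random lists of matched expression. Against the mean of all wells its median was -0.02, 0.13 and -0.18 in the IL-27 wells and 0.10 and -0.05 in the PBS wells, so the groups overlapped. None of its members differed by 1.5-fold, and edgeR with wells as replicates called 0 of them, adjusted over the list alone or over all genes. Among them Isg15 was 103 CPM in IL-27, 143 in PBS well 1 and 38.1 in PBS well 2, Irf7 73.3, 93.7 and 57.1, and Irf1 143 in IL-27 and 136 in PBS. Against PBS well 1 alone the interferon median was -0.13, and against PBS well 2 alone it was 0.05.

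Co-inhibitory and regulatory genes that IL-27 is known to induce in T cells showed no shared direction in CD4 T-like cells. Their median log2 ratio was -0.03 over 11 members (resampled range -0.36 to 0.12), at percentile 11.7 of the random lists, and 1 member was at least 1.5-fold lower. That member was Tigit, an inhibitory receptor, with 12.6 CPM in IL-27 and 28.4 in PBS, but 11.7 in PBS well 1 and 99.2 in PBS well 2. By edgeR 0 of the 11 were called, adjusted over the list alone or over all genes. Lag3 was 303 against 262 CPM, Pdcd1 113 against 132, and Maf, a transcription factor of Il10, 84.6 in IL-27, 91.3 in PBS well 1 and 195 in PBS well 2. The median was 0.13 against PBS well 1 and -0.46 against PBS well 2. Il10 itself was not detectable at this depth, with 1 UMI in 3638 IL-27 cells and 0 in 1110 PBS cells, and Il17a gave the same counts.

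Helper lineage lists in CD4 T-like cells gave different values against each PBS well. The Th1 list had a median log2 ratio of -0.16 over 7 members (resampled range -0.18 to -0.04, percentile 0.350), with 0.15 against PBS well 1 and -0.71 against PBS well 2. It was -1.43 with each library clustered on its own, -1.16 with CD4 T-like cells gated on UMIs and 0.020 among female-called cells. Ifng, the Th1 effector cytokine, was 2.83 CPM against 5.76 (45 and 30 UMIs), with a log2 ratio of -0.82, and -1.65 without PBS well 1. The naive and central memory list had a median of 0.15 over 15 members (0.07 to 0.21), at percentile 100, with 0.05 against PBS well 1 and 0.64 against PBS well 2. Its member Lef1, a factor of naive T cells, was 353 CPM in IL-27, 340 in PBS well 1 and 159 in PBS well 2, and Tcf7 and Klf2 were 586 against 529 and 474 against 406. None of the measured Th1 or naive members, which leave out Ifng for its low CPM, differed by 1.5-fold, and edgeR called 0 of each list, adjusted over the list alone or over all genes. The Tfh list had a median of -0.14 over 9 members, the cytotoxicity list -0.18 over 5, the exhaustion list 0.01 over 9, the Treg list -0.01 over 12 and the Th2 list 0.10 over 5. Against PBS well 1 alone these medians were -0.07, 0.17, 0.13, -0.03 and 0.25, in that order. Against PBS well 2 alone they were -0.48, -0.60, -0.46, -0.28 and -0.38. In the Th2 list Il4, the cytokine that defines Th2 cells, was 11.8 against 2.31 CPM, and in the cytotoxicity list Eomes was 18.0 against 9.99. Adjusted over the list alone, edgeR called Il4 and Igfbp7 in the Th2 list, Eomes in the cytotoxicity list and Angptl2 in the Tfh list, and over all genes it called 0 of them. The Th17 list had only 4 measured members, among them Ccr6 at 9.68 CPM in IL-27, 9.98 in PBS well 1 and 68.1 in PBS well 2.

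**Figure D4:**
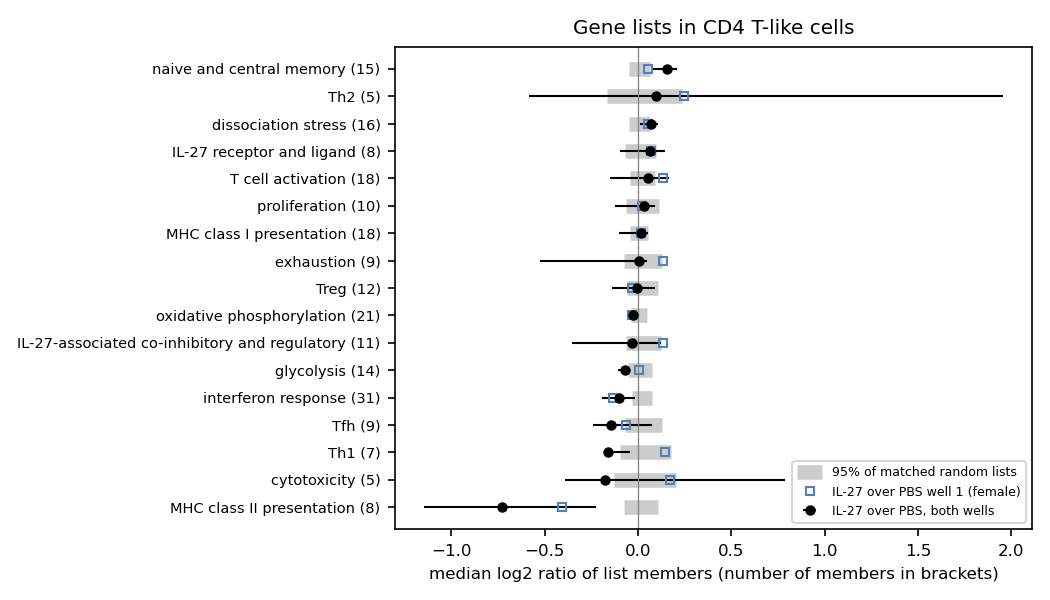
Median log2 ratio of IL-27 over PBS for the members of each gene list in CD4 T-like cells (black points, bars show the resampled range; squares use PBS well 1 alone; grey bands hold 95% of matched random lists). The MHC class II list lies lowest at -0.73 and the naive list highest at 0.15, and the Th1 and co-inhibitory medians are above 0 against PBS well 1 alone.

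The largest list difference in CD4 T-like cells was in MHC class II presentation, genes of antigen-presenting cells. Its median log2 ratio was -0.73 over 8 members, of which 4 were at least 1.5-fold lower, with -0.41 against PBS well 1. Adjusted over the list alone, edgeR called 5 of the 8 (H2-Aa, H2-Ab1, H2-Eb1, H2-DMa and Cd74), and over all genes 0. Cd74 was 304 CPM in IL-27, 467 in PBS well 1 and 1350 in PBS well 2, and H2-Aa 117, 181 and 591. Cd79a, a B cell gene, stood beside them at 72.8, 43.2 and 41.6 CPM in CD4 T-like cells of the IL-27 wells, 82.7 in PBS well 1 and 260 in PBS well 2. No doublet was removed from PBS well 2, so lower MHC class II RNA within T cells cannot be told apart from less B cell RNA among them. The same limit holds in Treg-like, CD8 T-like and NK-like cells, where Cd79a was also highest in PBS well 2. The other measured lists had medians near 0, with T cell activation at 0.05 over 18 members, proliferation 0.03 over 10, dissociation stress 0.07 over 16, MHC class I presentation 0.02 over 18, glycolysis -0.07 over 14 and oxidative phosphorylation -0.03 over 21. Within single lists edgeR called Irf8 of the activation list, Dusp1 of the stress list and Ighm and Ighd of the immunoglobulin list, and over all genes 0 of them. The myeloid, macrophage and immunoglobulin lists had 3, 1 and 2 measured members, and the gastric epithelial and erythroid lists 0.

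Noct, which encodes the rhythmically expressed phosphatase nocturnin, had by far the lowest ratio among CD4 T-like genes past the filter for named genes. It was 11.8 CPM in IL-27 (95% interval 10.1 to 13.6) and 69.0 in PBS (62.0 to 76.5), a PBS over IL-27 ratio of 5.87 (4.90 to 7.04). The IL-27 wells had 10.9, 9.64 and 14.8 CPM, PBS well 1 had 78.0 and PBS well 2 had 31.1. The PBS over IL-27 ratio was 5.12 in Treg-like, 3.97 in CD8 T-like, 5.35 in B-like and 2.33 in NK-like cells, and every IL-27 well lay below both PBS wells in CD4 T-like, Treg-like, CD8 T-like and B-like cells. Without PBS well 1 the log2 ratio in CD4 T-like cells was -1.33, against -2.46 with both PBS wells. In NK-like cells IL-27 well 3 (20.7 CPM) lay above PBS well 2 (13.9). By called sex, Noct in CD4 T-like cells was 12.2 CPM in female-called IL-27 cells, 75.7 in female-called cells of PBS well 1, 92.6 (55.7 to 145) in the 32 female-called cells of PBS well 2 and 14.1 (5.16 to 30.6) in its 78 male-called cells. Male-called cells had more Noct than female-called IL-27 cells in the Treg-like (57.0 against 14.9 CPM), CD8 T-like (48.0 against 12.2) and B-like classes (11.6 against 4.30). In NK-like cells they had 9.34 CPM (1.13 to 33.7) against 14.0. The CD8 T-like comparison sets unlike cells side by side, mostly cluster 15 in PBS well 2 and mostly cluster 5 in the IL-27 wells. With wells as replicates the adjusted p of Noct in CD4 T-like cells was 0.0850 by edgeR and 4.08e-05 by DESeq2. DESeq2 also called Noct lower in Treg-like (0.0128), CD8 T-like (0.0321) and B-like cells (1.88e-07), where edgeR did not call it (0.0657, 0.617 and 0.0661).

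**Figure D5:**
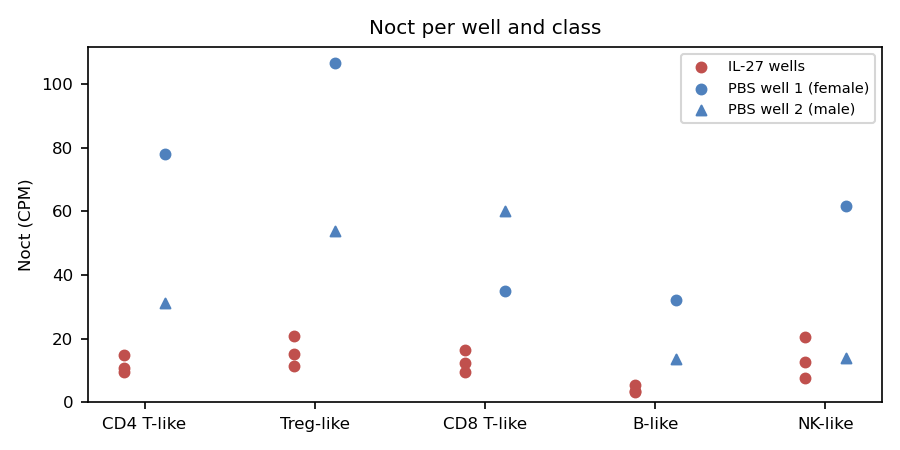
Noct expression (CPM) in 5 cell classes, with 1 point per well (IL-27 wells red, PBS well 1 blue circle, PBS well 2 blue triangle). In CD4 T-like cells the IL-27 wells sit at 9.64 to 14.8 CPM, PBS well 1 at 78.0 and PBS well 2 at 31.1.

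The remaining named genes of CD4 T-like cells differed by less. Among the 12 with the highest ratios were Kdm6b, a histone demethylase, at 97.3 against 69.7 CPM (log2 ratio 0.47), Nab2 at 117 against 86.3 (0.44), Midn at 72.6 against 53.4 (0.44), Ifngr2, a chain of the interferon gamma receptor, at 63.0 against 47.5 (0.40), and Bach2, a repressor of effector genes, at 76.7 against 59.4 (0.36). Kmt2a, Fam169b, Ppp3cc, Vps37b, Myb, Dnah8 and Plec had log2 ratios of 0.36 to 0.41, and Kmt2a, Ppp3cc and Myb overlapped between the wells of the groups. Without PBS well 1 the log2 ratio was 1.62 for Myb, 1.28 for Dnah8 and -0.16 for Ppp3cc. It was 0.62 for Kdm6b, 0.69 for Nab2, 0.68 for Midn, 0.83 for Ifngr2 and 0.92 for Bach2. Fam169b and Vps37b had 0.53 and 0.64, and Kmt2a and Plec fell to 0.21 and 0.31. Below Noct, the lowest were Alyref, an mRNA export factor (-0.72), Nrgn (-0.69), Thy1 (-0.61), Igfbp7 (-0.59), Taf10 (-0.58), Grb2 (-0.57), Cdc34 (-0.57), Tmem243 (-0.53), Tnfaip8 (-0.52), Cdk2ap1 (-0.48) and Rnf220 (-0.44), of which Nrgn, Thy1, Taf10, Grb2 and Rnf220 overlapped between the wells. Leaving out PBS well 1 gave -0.24 for Alyref, -0.34 for Nrgn, -0.07 for Taf10, -0.13 for Grb2, -0.16 for Cdc34 and -0.21 for Cdk2ap1. It gave -0.85 for Igfbp7, -0.90 for Tmem243 and -1.09 for Tnfaip8, and Rnf220 turned to 0.080. Thy1, a surface marker of T cells, was 380 CPM in PBS well 2, and its log2 ratio was 0.06 without that well and -1.98 without PBS well 1. Clustering each library on its own turned Ppp3cc to -0.20, Vps37b to -0.28, Nrgn to 2.6 and Igfbp7 to 0.60. With wells as replicates, edgeR called 0 of 10271 genes (442 at an unadjusted p under 0.05) and DESeq2 called 3, all lower in IL-27. They were Noct and the immunoglobulin genes Igkv12-44 and Igkv1-117, which B cells express. Without PBS well 2 edgeR called 2 genes, Noct (adjusted p 1.74e-04) and Igkv12-44, and without PBS well 1 it called 202.

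Most list values of Treg-like cells lay nearer 0 against the female PBS well than against the male PBS well. The naive and central memory list had a median log2 ratio of 0.56 over 13 members, 5 of them at least 1.5-fold higher, with 0.21 against PBS well 1 and 1.12 against PBS well 2. Satb1, a chromatin organiser, was 115 against 52.3 CPM and Tcf7 179 against 113. The co-inhibitory list had a median of -0.60 over 16 members, 8 of them at least 1.5-fold lower, with -0.17 against PBS well 1 and -1.16 against PBS well 2. Tigit was 230 CPM in IL-27, 254 in PBS well 1 and 811 in PBS well 2, and Maf 186, 218 and 495. The Th17 list had a median of -0.65 over 7 members, with 5 at least 1.5-fold lower, -0.70 against PBS well 1 and -1.01 against PBS well 2. Adjusted over the list alone, edgeR called Tcf7 and Satb1 in the naive list and Maf, Tigit, Pdcd1 and Ahr in the co-inhibitory list, and over all genes it called 0 of them. Foxp3, the Treg factor, was 249 against 304 CPM and Il27ra 272 against 240. Il10 was 3 UMIs in IL-27 and 25 in PBS, 24 of them in PBS well 2. MHC class II genes had a median of -0.40, and Cd79a was 45.2, 25.3 and 64.7 CPM in Treg-like cells of the IL-27 wells and 89.8 and 134 in PBS wells 1 and 2. The gastric epithelial gene Tff1 was 30.1, 7.37 and 2.97 CPM in the IL-27 wells and 14.1 and 101 in PBS wells 1 and 2. Within the gastric epithelial list edgeR called all 3 tested genes (Epcam, Tff1 and Gkn1), and over all genes 0 of them. Lad1, Satb1 and Gpr83 had the highest ratios (1.57, 1.12 and 0.84) and Lgals7, Noct and Igfbp7 the lowest (-2.79, -2.29 and -2.07), all of which moved with the PBS well. Without PBS well 1 they were 4.04, 2.05, 1.83, -3.86, -1.66 and -2.70, and without PBS well 2 0.86, 0.67, 0.38, -0.06, -2.63 and -1.29, in that order. Without IL-27 well 3 Lgals7 was -4.40, and Lad1 and Lgals7 overlapped between the wells of the groups. With wells as replicates edgeR called 1 of 8112 genes, Igkv3-2, an immunoglobulin gene (adjusted p 0.0433, lower in IL-27), and DESeq2 called 4, Noct, Arl5a, Ccl5 and Igkv3-2, all lower. Leaving out PBS well 1 gave 438 genes by edgeR, leaving out PBS well 2 gave 3 (Noct, Igkc and Iglv1), and leaving out any IL-27 well gave 0 (334 to 437 at an unadjusted p under 0.05).

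CD8 T-like values mirrored cluster 15, which held almost all CD8 T-like cells of the male PBS well and few of any other. The median log2 ratio of all genes in this class was -0.21, and values here are relative to it. Exhaustion genes had a median of -3.33 over 12 members, co-inhibitory genes -2.37 over 15, cytotoxicity genes -1.89 over 12, and naive genes 1.18 over 16. Adjusted over the list alone, edgeR called 7 of 11 tested exhaustion genes, among them Pdcd1 and Havcr2, and 0 in each of the other 3 lists. Over all genes it called 0. Against PBS well 1 the medians, not shifted, were 0.55, 0.32, -0.00 and 0.18. Lef1, Rflnb and Klhl6 had the highest relative ratios (1.45, 1.42 and 1.41), and Lef1 was 288, 297 and 282 CPM in the IL-27 wells, 222 in PBS well 1 and 21.02 in PBS well 2. Unshifted log2 ratios without PBS well 2 were 0.37 for Lef1, 0.47 for Rflnb and 0.48 for Klhl6, and without PBS well 1 they were 3.72, 2.76 and 2.70. Jchain, Coch and Lim2 had the lowest (-7.39, -5.76 and -5.50) and came almost only from PBS well 2. Without PBS well 2 the unshifted log2 ratio was 0.30 for Jchain and 0.87 for Coch. Within its own list edgeR also called 4 of 7 MHC class II genes (H2-Aa, H2-Ab1, H2-Eb1 and Cd74), and over all genes 0. Cd74 was 115, 150 and 129 CPM in the IL-27 wells and 204 and 1619 in PBS wells 1 and 2, and Cd79a 19.2, 27.0 and 17.4 against 34.5 and 273. Il27ra was 176 against 120 CPM, with 150 in PBS well 1 and 89.9 in PBS well 2. Il6st was 94.6 against 49.98 CPM, with 61.5 in PBS well 1 and 38.5 in PBS well 2. Without PBS well 2 their unshifted log2 ratios were 0.22 and 0.61. Ifng was 15.3 against 128 CPM, with 5.85 in PBS well 1 and 249 in PBS well 2. With wells as replicates edgeR called 0 of 8899 genes (710 at an unadjusted p under 0.05) and DESeq2 called 9. Without PBS well 1 edgeR called 3302 genes and without PBS well 2 it called 1, Myb.

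B-like cells differed little between the groups. Dnaja1, a heat shock cochaperone, was 166 against 115 CPM (log2 ratio 0.53), Il4i1 119 against 85.6 (0.47) and Itgb1bp1 51.9 against 37.5 (0.46), with 49.7 in PBS well 1 and 24.7 in PBS well 2 and a log2 ratio of 0.062 without PBS well 2. The log2 ratio of Dnaja1 was 0.31 without PBS well 2 and 0.79 without PBS well 1, and that of Il4i1 0.29 and 0.68. Tmem181a was 26.1 against 62.5 CPM (-1.23), with 26.8 in PBS well 1 and 100.2 in PBS well 2, and a log2 ratio of -0.036 without PBS well 2. Fos, an immediate early gene, was 40.3 against 61.1 CPM (-0.59) and the histone gene H3f3b 1356 against 1875 (-0.47), each with all IL-27 wells below both PBS wells. The interferon list had a median of -0.05 over 32 members, with Isg15 at 24.5 against 40.0 CPM and Ifit3, an antiviral effector, at 7.55 against 16.8. Adjusted over the list alone, edgeR called Ifit3, Isg15 and Usp18 of the interferon list, 7 of 17 dissociation stress genes (Fos, Fosb, Jun, Junb, Dnajb1, Dnaja1 and Socs3, with a list median of -0.10) and all 4 tested erythroid genes. The called stress genes shared no direction, with Dnaja1 (0.53) and Dnajb1 (0.38) higher in IL-27 and Fos (-0.59) and Jun (-0.39) lower. Over all 10697 genes edgeR called 0 (516 at an unadjusted p under 0.05), and DESeq2 called 7, all lower. They were Noct, H3f3b (adjusted p 5.03e-04), Ifit3 (0.0106), the Y-linked Eif2s3y and Ddx3y, and the immunoglobulin genes Igkv5-43 and Ighv9-1. Without PBS well 1 edgeR called 33 genes, without PBS well 2 it called 6 and without IL-27 well 1 it called 5, of which 4 were the haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt.

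NK-like cells, lymphocytes that kill without a rearranged receptor, were few (232 and 268). The interferon list had a median log2 ratio of 0.23 over 31 members (resampled range 0.16 to 0.30), and 0.19 against PBS well 1. Against the mean of all wells its median was -0.29, 0.27 and 0.09 in the IL-27 wells and -0.13 and -0.16 in the PBS wells, so the groups overlapped. Isg15 was 20.9, 72.4 and 41.4 CPM in the IL-27 wells and 27.0 and 5.97 in PBS wells 1 and 2. By edgeR 0 of 23 tested members were called, adjusted over the list alone or over all genes. MHC class II genes had a median of -2.05 over 8 members, 6 of them at least 1.5-fold lower, and -0.89 against PBS well 1. Cd79a stood beside them at 54.4, 11.4 and 93.1 CPM in NK-like cells of the IL-27 wells and 92.5 and 318 in PBS wells 1 and 2. Stmn1, Lef1 and Cuedc1 had the highest log2 ratios (0.95, 0.82 and 0.82), and Thy1, the chemokine gene Ccl4 and Cdk13 the lowest (-2.24, -1.19 and -0.996). Thy1 was -0.91 and Ccl4 -0.39 without PBS well 2, and Ccl4 overlapped between the wells of the groups. With wells as replicates edgeR called 8 of 4541 genes. Thy1, H2-Aa, H2-Ab1, H2-Eb1, Cd74, Cd79a and Litaf were lower in IL-27 and Gpr25 was higher, with adjusted p from 0.00671 for H2-Eb1 to 0.0413 for Litaf. Cd79a, Cd74 and H2-Aa were highest in PBS well 2, from which no doublet was removed. For the MHC class II genes and Cd79a, a change within NK-like cells cannot be told apart from B cell RNA among them. DESeq2 called 0 (62 at an unadjusted p under 0.05), and edgeR called 0 without IL-27 well 1 (242 at an unadjusted p under 0.05) or without IL-27 well 2 (229), 13 without IL-27 well 3 and 35 without PBS well 1. Without PBS well 2 it called 7, of which 2 (H2-Aa and H2-Eb1) were among the 8.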

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

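All tests of explanations in this part were chosen after the results were seen.

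PBS well 2, the well with Y-linked RNA, held 183 cells with Xist and no Y-linked UMI, a signal outside the planned comparisons and above the limit that a count of 0 allows. Tests argued against barcodes read out in the wrong well, since 4.37% of these cells shared a barcode with another well (upper limit 8.43%, 8 cells where 6.73 were expected by chance). They also argued against free Xist RNA, since Xist was found in 0.689% of cells with Y-linked UMIs and 5.59% of cells without. Cells carried over from a female mouse may account for them, since 17.5% of these cells were CD4 T-like, against 3.61% of male-called cells. When and how such cells entered was not tested, and no biological explanation was tested.

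Mast cell-like cells and cluster 15, a CD8 T-like cluster, came almost wholly from PBS well 2. Doublets in place of the mast cell-like cells were argued against, since these had a median of 1632 UMIs (1227 to 1856) against 3135 in other cells of that well. Trbv30 in cluster 15 lay above all other T clusters of the well, with clusters 18, 21 and 26 pooled (lower limit 33.2%, others at most 6.06%). Trbv30 was chosen after its values were seen, so its rank is no independent test. It also could not exclude T cells joined to B cells. Cd79a was 273 CPM in CD8 T-like cells of PBS well 2 and 34.5 in those of PBS well 1. Doublets in cluster 15 therefore stay open. More gastric lining tissue in the flush stays open, since 15 gastric epithelial genes summed to 38.1 CPM in PBS well 2, 46.0, 13.9 and 8.90 in the IL-27 wells and 9.53 in PBS well 1. The sex of the mouse and the single mouse cannot be told apart, because the series has 1 male. Trbv30 gave 35.0% of Trbv UMIs in cluster 15 of PBS well 2 (945 of 2702), a signal outside the planned comparisons, and 0 of 385 in cluster 15 of IL-27 and 0 of 89 in that of PBS well 1.

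Noct was lower in CD4 T-like cells of every IL-27 well than in either PBS well. A weaker stress response was argued against in this class alone, since the dissociation stress list had a median log2 ratio of 0.0687 here but -0.25 in Treg-like, -0.10 in B-like and -0.36 in NK-like cells. Sex alone was argued against as well, since the female PBS well had 5.28 times (4.09 to 6.91) the Noct of the highest IL-27 well. Male-called CD4 T-like cells of PBS well 2 had 14.1 CPM and its female-called cells 92.6, so the PBS well 2 value of 31.1 mixed unlike cells, and the difference in this class rests on RNA of female PBS cells. Time of day stays open. Clock output genes had an IL-27 over PBS ratio of 1.18 (1.03 to 1.35) in CD4 T-like cells and 1.04 (0.968 to 1.12) in B-like cells, but 0.764 in Treg-like cells. A further clock list (Arntl, Npas2, Clock, Cry1 and Nfil3) had a ratio of 1.01 (0.897 to 1.15) in CD4 T-like cells. Its ratio was 0.971 in Treg-like and 0.987 (0.909 to 1.07) in B-like cells, but 0.523 in CD8 T-like cells. Cluster 15 made up 90.8% of the CD8 T-like cells of PBS well 2, so that value cannot separate time of day from cell type. IL-27 treatment, a trait of a single female PBS mouse, and cage or processing day stay open too. IL-27 is a hypothesis that more PBS females would test.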

How the results depend on the processing

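The left-out wells, the common doublet threshold, equal weighting of wells and the tests between wells were chosen after the data had been seen. No paired analysis was possible because the mice of the groups were not matched. Of 134 alternative values of the main results 97 stayed within the spread, 35 moved and 2 reversed, and of 1304 values of 64 named-gene results 1027 stayed, 259 moved and 18 reversed. The 134 include the counts of genes called between wells by DESeq2 and by edgeR without the low-count filter. They exclude values with 1 well left out, which the 1304 include. Except where stated, the cause was not tested. The CD4 T-like ratio of 1.92 was 2.28 at Leiden resolution 0.5, 2.12 at resolution 2, 2.95 with each library clustered on its own, 2.15 with a doublet score threshold of 0.25 in every well and 1.16 among female-called cells. The Treg-like ratio reversed to 0.920 at the doublet threshold of 0.25. The CD8 T-like ratio was 2.69 at 5% mitochondrial UMIs, 1.24 with libraries clustered on their own and 1.60 among female-called cells. The B-like ratio was 0.875, 0.884 and 0.892 at 5% mitochondrial UMIs, at resolution 2 and with own clustering. The NK-like ratio was 0.340 at resolution 0.5 and 0.715 among female-called cells, and the mast cell-like ratio 0.318 among female-called cells. That mast cell-like ratio rests on only 3 IL-27 and 3 PBS cells. Leaving out 1 well at a time gave 1.25 to 4.94 for CD4 T-like, 1.21 to 1.62 for Treg-like, 1.16 to 1.65 for CD8 T-like, 0.798 to 0.875 for B-like, 0.377 to 0.725 for NK-like and 0.0221 to 0.859 for mast cell-like cells.

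In CD4 T-like cells the interferon median was -0.43 with own clustering and -0.14 to 0.051 with 1 well left out. The co-inhibitory median was 0.14 at resolution 0.5, 0.16 among female-called cells and -0.54 to 0.13 with 1 well left out. The Th1 median was -1.43 with own clustering, -1.16 with a UMI gate (2090 and 698 cells), -0.19 when centred, -0.33 in thinned cells, -0.53 with wells weighted equally, 0.020 among female-called cells and -1.08 to 0.15 with 1 well left out. The naive median was 0.059 with own clustering, 0.29 with the gate, 0.039 among female-called cells, 0.35 with wells weighted equally and 0.054 to 0.64 with 1 well left out. Named genes reversed with own clustering in CD4 T-like cells (Ppp3cc -0.20, Vps37b -0.28, Nrgn 2.60, Igfbp7 0.60) and among female-called cells (Thy1 0.084 in CD4 T-like, Jchain 0.24 and Penk 2.49 in CD8 T-like). With 1 well left out they ranged from -0.16 (without PBS well 1) to 0.57 for Ppp3cc, -0.55 to 0.080 (without PBS well 1) for Rnf220 and -1.98 to 0.058 (without PBS well 2) for Thy1 in CD4 T-like cells, and -0.67 to 0.12 (without PBS well 1) for Taf10 in B-like cells. Without PBS well 2 the upper ends were 0.042 for Ccl1 in Treg-like cells (from -2.43) and, in CD8 T-like cells, 0.30 for Jchain (from -8.60), 0.87 for Coch (from -6.96), 0.44 for Fcrl6 (from -6.62) and 1.73 for Penk (from -6.49). Jchain was 0.15 at 5% mitochondrial UMIs and Stmn1 -0.12 in thinned NK-like cells. Noct in CD4 T-like cells ranged from -2.67 to -1.33 over its alternatives.

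Genes called between wells, by edgeR, DESeq2, edgeR without the low-count filter, and edgeR with 1 well left out, were 0, 3, 135 and 0 to 202 in CD4 T-like cells, 1, 4, 160 and 0 to 438 in Treg-like cells, 0, 9, 0 and 0 to 3302 in CD8 T-like cells, 0, 7, 53 and 0 to 33 in B-like cells, and 8, 0, 32 and 0 to 35 in NK-like cells. Where edgeR called 0, 442, 710 and 516 genes had an unadjusted p under 0.05 in CD4 T-like, CD8 T-like and B-like cells, and 1336 in CD8 T-like cells without the filter. DESeq2 had 62 in NK-like cells. With a PBS well left out, its partner is a lone sample assumed to vary like the IL-27 wells.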

Other observations

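No test in this part was planned, and the clusters and genes were chosen after their values were seen. Cluster 24, unnamed and with Rgs13, Mef2b and S1pr2 among its leading genes, genes known from germinal centre B cells, was 0.681% of IL-27 cells (136 cells) and 0.0513% of PBS cells (6 cells), a ratio of 13.3 (5.94 to 36.8). It was 0.553%, 0.205% and 1.22% of the IL-27 wells, 0.0961% of PBS well 1 and 0 of PBS well 2, where the limit is 0.0550%. The ratio was 7.74 without IL-27 well 3 and 7.08 without PBS well 2. Plasma cell-like cells, which secrete antibody, had Ighg1 as 67.4% of heavy chain UMIs in the IL-27 library (36 cells) and 0.191% in the PBS library (14 cells). By well these were 75.5%, 55.0% and 69.2% against 0.426% and 0 of 2319 UMIs. Ighm was 0, 0.782% and 6.91% in the IL-27 wells against 66.5% and 36.6% in the PBS wells. Igha was 24.5%, 44.2% and 16.9% in the IL-27 wells against 9.65% and 63.3% in the PBS wells. PBS well 1 also had Ighg2b at 11.7% and Ighg2c at 9.49%, so heavy chains other than Ighm were present in both groups. These shares rest on 2 to 25 cells per well, and 1 cell can supply many of the UMIs.

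Cluster 26, an unnamed T cluster led by Ifit1, Ifit3 and Isg15, was 0.496% of IL-27 and 0.137% of PBS cells, with 1.38% in IL-27 well 2 and at most 0.192% in any other well, and its ratio was 3.62 with all wells and 0.932 without IL-27 well 2. Cluster 18, an unnamed T cluster with a median of 888 UMIs, was 1.51% against 0.222%, with 2.65%, 1.16% and 0.596% in the IL-27 wells, and its ratio of 6.78 was 3.85 without IL-27 well 1. Cluster 19, unnamed and of myeloid type, was 0.766% of IL-27 cells, 0.577% of PBS well 1 and 2.24% of PBS well 2. Cluster 6, an unnamed B-lineage cluster, was 4.10% of IL-27 cells, 3.41% of PBS well 1 and 11.8% of PBS well 2. Trbv1 gave 41.3% of Trbv UMIs in CD4 T-like cells of IL-27 and 44.4% in those of PBS. Haemoglobin and Alas2 RNA summed to 0.113, 155 and 381 CPM in the IL-27 wells and 1.61 and 3.50 in PBS wells 1 and 2.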
